A study of Mus musculus with 12 samples.

How the data were processed

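Renal cortex RNA of 12 mouse samples was measured on Affymetrix gene arrays, 3 arrays in each of 4 groups. The groups were control and GR-deficient mice, healthy or 24 hours after intramuscular glycerol. Groups and replicate numbers were taken from the sample labels, and all 12 value columns were mapped to a sample.

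The values are log2 expression values that the authors deposited, made by robust multichip averaging (RMA) with the R packages affy and oligo, per the submitters' processing notes. Versions of these tools are not given in the sources used here. RMA corrects background, normalizes the arrays to each other and summarises probes to 1 value per probe set. The file does not state the log base. The largest value on each array lay between 14.73 and 14.9, which is the range of a log2 scale. No further normalization was applied. The raw scans were not used here.

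Of 35556 probe sets in the value table, 23410 had an entry in the probe-gene table, 21789 with exactly 1 gene symbol and 1621 with several, and 12146 had none. Of the 1-symbol probe sets, 21698 had an Entrez ID found in the RefSeq table, and 0 symbols needed updating. Where a gene had several such probe sets (999 genes), the one with the highest mean over all 12 arrays was kept. This left 19938 genes, with no filter on dim genes.

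Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with the default prior) on a model with 4 group means. The fit had 8 residual degrees of freedom and 6.26 prior degrees of freedom. A set of 6 contrasts was tested: AKI against healthy in each genotype, GR-deficient against control in each condition, the interaction, and the genotype effect averaged over both conditions with equal weight. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes within a contrast, with a threshold of 0.05, and every p-value in the text is from these moderated tests or from limma set tests, except 2 permutation tests and 1 exact binomial test named where they are given. The count that also differed by at least 1 on the log2 scale is given beside each count.

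A set of 29 gene lists was fixed before the data were examined, from general knowledge of kidney biology. Red blood cells were not tested, since of that list only Alas2 was measured, and the sex-linked genes served as a check of each array. The other 27 lists were tested with camera with its preset correlation of 0.01, adjusted over the lists within a contrast. Camera compares a list with all other genes. Camera with a correlation estimated from these arrays, and fry, which tests a list on its own, served as alternatives. Counts of members are given over all genes and adjusted over the list alone. List members without a probe set of exactly 1 symbol, such as Spp1, Gdf15, C3 and Cdkn1a, were not analysed here.

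The genes named in the text followed a rule fixed before the data were examined. They are Nr3c1, the 10 genes with the largest positive and the 10 with the largest negative difference among those that passed and whose arrays did not overlap between the 2 groups (no such condition for the interaction and the average), and the members of described lists with the smallest p, up to 4 for the 5 main lists and 2 for others. Predicted genes, clone names, microRNA, snoRNA and receptor segments were skipped. For the average, only some of the genes that the rule gives are printed. Other genes are named for a stated reason: checks of single arrays, clock genes and deviation from a common factor.

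The response of GR-deficient mice was compared with that of control mice by the slope through the origin over genes that passed and changed at least 2-fold in control mice. The deviation of each gene from this common factor was tested in the same fit as the GR-deficient response minus the factor times the control response.

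The fits were tested on simulated data with the size and spread of these arrays (19938 genes, 200 of them changed, 50 of each size). For a change of 1 on the log2 scale the share recovered was 88% for AKI in control mice, 92% for AKI in GR-deficient mice, 94% for GR deficiency in healthy mice, 92% for GR deficiency in AKI, 68% for the interaction and 98% for the average. For a change of 0.5 these shares were 38%, 44%, 34%, 22%, 6% and 76%, so in the simulation such changes were mostly missed except in the average. The adjusted threshold is stricter when few genes change, so the shares may be too low for real contrasts in which far more than 200 genes passed. The simulated noise also had the same spread on every array. False calls numbered 3 to 17 per contrast, the most being 17 of 173 calls for GR deficiency in AKI. Camera was tested on 20 simulated lists, of which the 1 changed list had an adjusted p of 1.4e-39 and the lowest of the other 19 was 0.619. Noise was drawn independently for each gene, so the simulation cannot test camera on lists whose members vary together. In the real data the estimated correlation was, for example, 0.512 for proximal tubule genes after AKI in control mice. Fry was not tested in this way. The number of arrays, 3 per group, sets this precision.

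Within groups the arrays correlated with r from 0.9837 to 0.9955 over genes, and 0 pairs had identical values. Alternatives were all probe sets, the mean of a gene's probe sets, dim genes (below the 30th percentile) left out, arrays centred on their medians, quantile normalization, cyclic loess, an intensity trend with a robust prior, array quality weights, the replicate number as a block, each array left out in turn, fits on only the 6 arrays compared, and a test against a change above 1.2-fold. A fit without 2 doubted arrays (control AKI replicate 1 and GR-deficient healthy replicate 1) was added after their correlations and principal components had been seen. Group labels were also reassigned, in all 10 splits for a comparison of 2 groups. For the interaction and the average 100 of 200 splits were used, the real one and others drawn at random.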

Results

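Expression was measured on 12 Affymetrix mouse gene arrays hybridised with amplified renal cortex RNA, 3 arrays in each of 4 groups. Control mice carried floxed alleles of Nr3c1, the gene of the glucocorticoid receptor (GR). GR-deficient mice carried the same floxed alleles together with Pax8-Cre, a recombinase expressed in renal tubular epithelium. Differences between the genotypes therefore include any effect of Pax8-Cre itself. Cortices came from uninjected (healthy) mice or from mice 24 hours after glycerol was injected into muscle, which breaks down muscle and loads the kidney with myoglobin (acute kidney injury, AKI). The healthy mice formed a separate cohort per the labels, so a difference after AKI includes any difference between the cohorts. The labels number the replicates of a group and do not say that each is a separate animal, so p-values measure only the spread between these samples, which may be technical. Values are deposited log2 expression values, and all differences below are on the log2 scale with a standard error (SE) from the limma fit. The number of arrays limits the precision.

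The medians of the arrays over 19938 genes lay between 7.001 and 7.092. A pair of arrays stood apart from their groups. Control AKI replicate 1 had the narrowest spread over genes (SD 1.88 against 1.96 to 2.06 in the other 11 arrays) and the highest value on the second principal component (33.8, with 11.6 the next highest). GR-deficient healthy replicate 1 had the highest value on the third component (34.8, with 5.83 the next highest), and it held more Lcn2 (9.94 against a mean of 7.09 in the other 2 arrays of its group), more Havcr1 (8.11 against 6.39) and more Krt20 (6.46 against 5.35). Of the sex-linked genes, Xist lay between 3.99 and 4.41 and the Y-linked gene Eif2s3y between 7.70 and 8.88 on every array. Low Xist with a Y-linked gene present is the pattern of male samples, on all 12 arrays. The Y-linked genes Kdm5d (6.02, 6.11 and 6.04) and Uty (7.21, 7.62 and 7.88) were low on the control AKI arrays, against 6.42 to 6.91 and 7.70 to 8.41 on the other 9. Kdm5d thus set that group apart in level, though Xist and Eif2s3y show no difference in sex.

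Nr3c1, the targeted gene, was lower on every GR-deficient array than on any control array. Its log2 values were 9.65, 9.48 and 9.52 in healthy control mice, 8.82, 8.89 and 8.86 in control mice with AKI, 8.18, 8.13 and 8.21 in healthy GR-deficient mice and 8.10, 7.96 and 7.87 in GR-deficient mice with AKI. GR deficiency lowered it by 1.38 ± 0.097 in healthy mice (adjusted p = 1.73e-05) and by 0.88 ± 0.097 in AKI (adjusted p = 2.69e-05, limma, n = 3 per group). Where the probes lie relative to the floxed part was not analysed here, and the cortex also holds cells outside the tubule in which Pax8-Cre is not expressed.

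**Figure D1:**
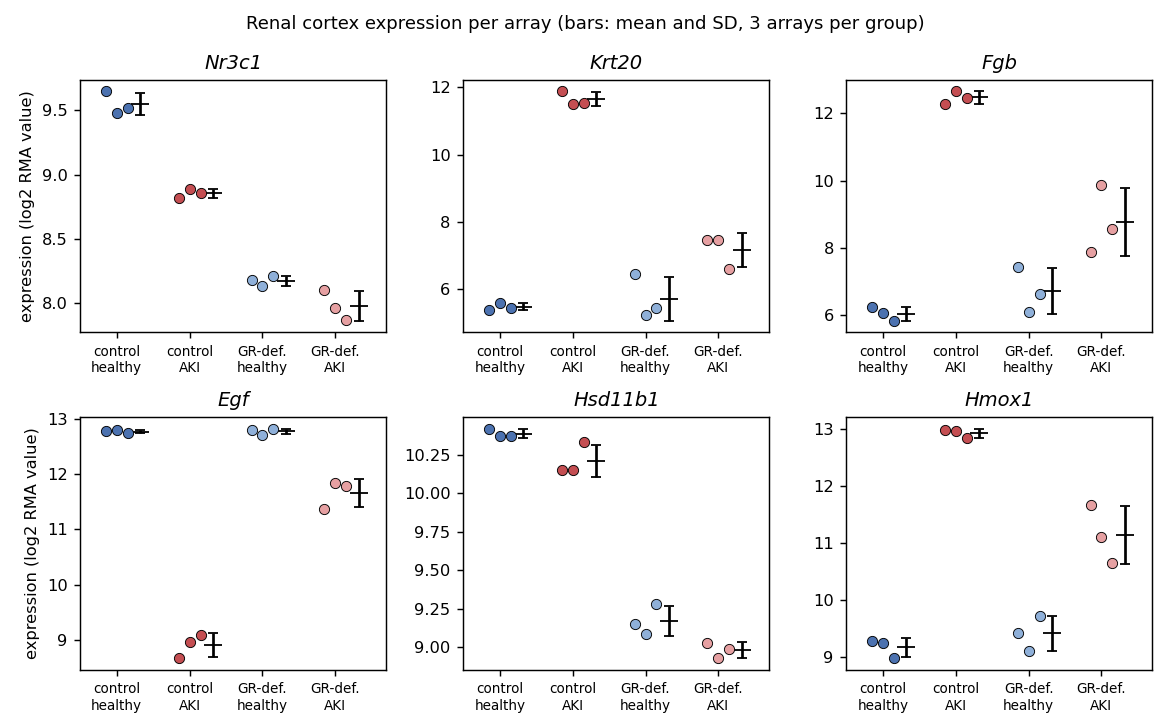
Log2 expression value (y axis) of 6 genes on each of the 12 arrays by group (x axis), where points are arrays and bars give the mean and SD of 3 arrays. Nr3c1 lay between 7.87 and 8.21 on the GR-deficient arrays and between 8.82 and 9.65 on the control arrays, and Krt20 and Fgb were highest in control mice with AKI.

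The first comparison asked what AKI changed in control mice. Fibrinogen chain genes and markers of injured tubule rose most. Fgb (6.43 ± 0.39), Fgg (6.16 ± 0.53) and Fga (4.42 ± 0.32) encode the 3 fibrinogen chains. Krt20 (6.15 ± 0.28) encodes an epithelial keratin, Havcr1 (6.12 ± 0.46) the kidney injury molecule KIM-1 and Lcn2 (5.99 ± 0.55) the iron-carrier binding protein NGAL. The stress genes Hspb1 (4.39 ± 0.24), a small heat shock protein, Akr1b8 (4.23 ± 0.21), an aldo-keto reductase, and Slc7a11 (4.15 ± 0.35), the cystine transporter, rose as well. Lrg1 (4.39 ± 0.28), a secreted glycoprotein of the acute phase, was also among the 10 largest increases. Among the genes that fell most, Hsd3b2 (-4.07 ± 0.22) and Hsd3b3 (-3.34 ± 0.22) belong to a family of steroid dehydrogenases, and Egf (-3.86 ± 0.13) encodes a growth factor made in the distal nephron. Lower as well were Sucnr1 (-3.53 ± 0.2), the succinate receptor, Gatm (-3.47 ± 0.21), a creatine synthesis enzyme, and Cndp1 (-3.39 ± 0.18), a carnosine dipeptidase. Also among the 10 largest decreases were Hykk (-3.34), Sectm1b (-3.24), St8sia1 (-3.18) and Car3 (-3.17), with adjusted p from 9.48e-10 to 1.95e-05 over the 10. Genes were named for their size in a comparison of 2 groups only if the 3 arrays of one group did not overlap the 3 of the other. Chance alone gives this for 10% of genes, and as a condition of choice it adds no support.

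In all, 5715 of 19938 genes passed an adjusted p of 0.05 in control mice, 2708 higher and 3007 lower after AKI, and 1306 of them differed at least 2-fold (519 higher and 787 lower). The larger side was the higher one after quantile normalization (3061 higher and 2996 lower) and over all probe sets (3441 and 3223). Nr3c1 itself fell by 0.69 ± 0.097 (adjusted p = 6.56e-05). Of the 27 gene lists tested, 17 passed camera with its preset correlation and none passed with a correlation estimated from these arrays, where 8 residual degrees of freedom remain. That loss holds for each list called below, and its p is given beside each.

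Among tubular injury markers, 18 of 19 measured members rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 3.81e-18, adjusted p = 0.0685 with an estimated correlation). Examples were Sox9 (2.63), a transcription factor of regenerating tubule, Tnfrsf12a (3.61), the TWEAK receptor, and Plaur (3.53), the urokinase receptor. In the acute phase and complement list, which holds the fibrinogen genes and Lrg1, 14 of 16 rose and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 6.4e-11, and adjusted p = 0.0685 with an estimated correlation). For the heme and antioxidant response, 11 of 15 measured members rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 3.16e-09, adjusted p = 0.0807 with an estimated correlation). Its leading members were Hmox1 (3.77), heme oxygenase 1, Srxn1 (3.48), Nqo1 (1.78) and Txnrd1 (1.81), the last 3 being targets of the oxidative stress factor NRF2. In the list of the unfolded protein and integrated stress response 14 of 18 rose and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 5.02e-09, and adjusted p = 0.0877 with an estimated correlation). Atf3 (3.50) and Atf4 (1.49) were among them. Among heat shock genes, 8 of 11 rose and 0 fell (8 and 0 adjusted over the list alone, adjusted p = 3.04e-05, and adjusted p = 0.176 with an estimated correlation). Hspa1a (2.89), an inducible chaperone, rose. Of p53 targets and growth arrest genes, 9 of 15 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 6.76e-05, and adjusted p = 0.116 with an estimated correlation). Plk3 (3.25) and Btg2 (1.58) were among them.

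Genes of regulated cell death moved both ways: 6 of 19 measured members rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00506, adjusted p = 0.0768 with an estimated correlation). Mlkl (2.70), the executor of necroptosis, and the ferroptosis gene Acsl4 (1.51) rose, whereas Dpep1 (-1.51), a brush border dipeptidase, fell. Among glucocorticoid receptor targets, 12 of 23 measured members rose and 6 fell (13 and 6 adjusted over the list alone, camera adjusted p = 0.00887, adjusted p = 0.116 with an estimated correlation). The 4 members with the smallest p all rose: the metallothioneins Mt2 (2.84) and Mt1 (1.92), Map3k6 (1.95) and Pdk4 (3.58), a kinase that restrains glucose oxidation. Proximal tubule genes fell without exception: 0 of 23 rose and 23 fell (0 and 23 adjusted over the list alone, adjusted p = 3.62e-19, and adjusted p = 0.0807 with an estimated correlation). Examples were Miox (-2.25), an inositol oxygenase, Slc5a2 (-2.07), the glucose transporter SGLT2, Slc7a13 (-2.60) and the water channel Aqp1 (-1.71). In the loop, distal tubule and collecting duct list 0 of 20 rose and 14 fell (0 and 15 adjusted over the list alone, adjusted p = 6.23e-10, and adjusted p = 0.0685 with an estimated correlation). Slc12a1 (-2.89), the NKCC2 cotransporter, fell next to Egf.

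Energy metabolism genes were lower. For gluconeogenesis 0 of 10 rose and 9 fell (0 and 9 adjusted over the list alone, adjusted p = 2.09e-07, and adjusted p = 0.0877 with an estimated correlation). Mdh1 (-1.04) and Klf15 (-1.80) were among them. For oxidative phosphorylation 0 of 18 rose and 16 fell (0 and 17 adjusted over the list alone, adjusted p = 2.06e-09, and adjusted p = 0.0846 with an estimated correlation). Ndufs1 (-1.09) and Sdhb (-0.77) were among them. For fatty acid oxidation 1 of 18 rose and 9 fell (1 and 9 adjusted over the list alone, adjusted p = 0.00297, and adjusted p = 0.473 with an estimated correlation), with Fabp3 (-2.08) and Acadm (-0.96), and the list no longer passed after quantile normalization (adjusted p = 0.0783), after cyclic loess (0.0714) or without control AKI replicate 1 (0.0883). Of circadian clock genes, 3 of 15 rose and 10 fell (4 and 10 adjusted over the list alone, adjusted p = 0.00614, and adjusted p = 0.0807 with an estimated correlation), and the clock output factors Tef (-2.44) and Dbp (-2.69) fell.

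Genes of neutrophils and of inflammation also rose with AKI in control mice. Of neutrophil genes, 9 of 13 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 7.28e-06, and adjusted p = 0.0846 with an estimated correlation). S100a8 (2.05) and S100a9 (1.76) were among them. Among cytokines, chemokines and adhesion molecules, 9 of 20 rose and 0 fell (9 and 1 adjusted over the list alone, adjusted p = 0.000367, and adjusted p = 0.0807 with an estimated correlation), led by Cxcl1 (2.09) and Il6 (2.03). In the list of monocytes and macrophages, 5 of 17 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.0488, and adjusted p = 0.378 with an estimated correlation), and Cd68 (2.85) and Cd14 (3.92) rose. That list did not pass after quantile normalization (adjusted p = 0.0804) or cyclic loess (0.0811), nor without control AKI replicate 2 (0.0948), control AKI replicate 3 (0.0776) or healthy control replicate 3 (0.102).

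The remaining 10 lists did not pass in control mice. Corticosteroid receptors and steroid handling had 3 of 10 rising and 3 falling (3 and 5 adjusted over the list alone, camera adjusted p = 0.177), with a decrease of Hsd11b2 (-1.45), the enzyme that inactivates glucocorticoids in the distal nephron. The interferon response had 1 of 13 rising and 1 falling (1 and 1 adjusted over the list alone, camera adjusted p = 0.489), with Rsad2 (-1.45) and Bst2 (0.89) moving apart. Proliferation genes had 2 of 20 rising and 0 falling (1 and 0 adjusted over the list alone, camera adjusted p = 0.916). Among markers of other cells, endothelium had 5 of 15 rising and 4 falling (6 and 4 adjusted over the list alone, camera adjusted p = 0.729), with Kdr (-0.94) and Nos3 (1.01) in opposite directions and a median (0.104) and mean (-0.0142) of opposite sign. Fibroblasts, mural cells and matrix had 5 of 15 rising and 4 falling (5 and 4 adjusted over the list alone, camera adjusted p = 0.492), with increases of Pdgfrb (1.02) and Col3a1 (0.93). Podocytes had 1 of 9 rising and 3 falling (2 and 3 adjusted over the list alone, camera adjusted p = 0.681), with Clic5 (-1.23) lower. Lymphocytes had 0 of 14 rising and 0 falling (0 and 0 adjusted over the list alone, camera adjusted p = 0.373) and skeletal muscle 0 of 10 rising and 0 falling (0 and 0 adjusted over the list alone, camera adjusted p = 0.916). Adrenal gland genes had 2 of 8 rising and 0 falling (2 and 0 adjusted over the list alone, camera adjusted p = 0.744) and adipocyte genes 1 of 6 rising and 0 falling (1 and 0 adjusted over the list alone, camera adjusted p = 0.882), the latter with a median (-0.14) and mean (0.0416) of opposite sign.

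The next comparison asked the same of GR-deficient mice. The injury markers Lcn2 (3.7 ± 0.55), Havcr1 (3.50 ± 0.46), Timp1 (2.04 ± 0.3), a protease inhibitor, and Tnfrsf12a (1.98 ± 0.21) rose, as did Akr1b8 (2.23 ± 0.21) and Fgb (2.05 ± 0.39). Also among the 10 largest increases were Cyp4a14 (2.82 ± 0.56), a fatty acid hydroxylase, Ces1g (2.31 ± 0.23), a carboxylesterase, Aldh1a2 (2.04 ± 0.27), a retinoic acid synthesis enzyme, and Slc16a6 (1.90 ± 0.2), a transporter of ketone bodies. The largest decreases were Ccl28 (-2.04 ± 0.47), an epithelial chemokine, and Ttr (-2.03 ± 0.18), the thyroid hormone carrier transthyretin. Car3 (-1.98 ± 0.39), a carbonic anhydrase, Upp2 (-1.64 ± 0.17), a uridine phosphorylase, and Pzp (-1.56 ± 0.2), a protease inhibitor, also fell. They were followed by Akr1c18 (-1.51), Bcat1 (-1.40), Akr1c14 (-1.36), Fcamr (-1.34) and Omd (-1.32).

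Of 19938 genes, 926 passed, 656 higher and 270 lower after AKI, and 135 of them differed at least 2-fold (109 and 26), and 88 without GR-deficient AKI replicate 1. The share of higher genes was 70.8%, and it was 60.2% after quantile normalization (659 higher and 436 lower) and 60.6% after cyclic loess (687 and 447). With array quality weights it was 56.1% (1793 and 1403), and against a change above 1.2-fold it was 81% (124 and 29). The count was 277 without GR-deficient AKI replicate 1, 468 without GR-deficient AKI replicate 2 and 472 without GR-deficient healthy replicate 2. Of the 57 named genes called here, 39 passed in every fit that left out 1 array. Cyp4a14 no longer passed without GR-deficient AKI replicate 1 or healthy replicate 1, Car3 without AKI replicate 1 or healthy replicate 2, and Ccl28 without any of 4 arrays (AKI replicates 1 and 3, healthy replicates 2 and 3).

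For the heme and antioxidant response in GR-deficient mice, 10 of 15 measured members rose and 0 fell (13 and 1 adjusted over the list alone, camera adjusted p = 5.46e-15, adjusted p = 0.0691 with an estimated correlation). Members were Nqo1 (1.66), Srxn1 (1.76), Hmox1 (1.73) and the efflux pump Abcc4 (1.13). Among tubular injury markers, 10 of 19 measured members rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 5.46e-15, adjusted p = 0.0983 with an estimated correlation). In the regulated cell death list, 4 of 19 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.0015, and adjusted p = 0.0691 with an estimated correlation), and Mlkl (1.11), Acsl4 (0.60), Slc7a11 (1.86) and the transferrin receptor Tfrc (0.99) rose, the last not without GR-deficient AKI replicate 1. Proximal tubule genes had smaller decreases: 0 of 23 rose and 4 fell (0 and 9 adjusted over the list alone, adjusted p = 0.000297, and adjusted p = 0.506 with an estimated correlation), namely Slc5a2 (-0.64), Cyp2e1 (-0.72), Cyp4b1 (-0.56) and Miox (-0.46). Each of these 4 lost its call when GR-deficient AKI replicate 1 was left out, and also without other arrays. Of the 6 fits without 1 array, Slc5a2 and Cyp2e1 passed in 4, Cyp4b1 in 2 and Miox in 1. Of glucocorticoid receptor targets, 4 of 23 rose and 2 fell (5 and 6 adjusted over the list alone, adjusted p = 0.902, and adjusted p = 0.935 with an estimated correlation). Mt2 (1.42), Mt1 (0.72) and Pdk4 (1.69) rose (Mt1 not without GR-deficient AKI replicate 1), Klf15 (-0.88) fell, and the median of the list (-0.0493) and its mean (0.0185) differed in sign.

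Other lists that passed with the preset correlation were led by the unfolded protein and integrated stress response, where 4 of 18 rose and 0 fell (11 and 0 adjusted over the list alone, adjusted p = 2.13e-07, and adjusted p = 0.191 with an estimated correlation). Xbp1 (1.16) and Asns (1.21) were among them. For acute phase and complement 5 of 16 rose and 0 fell (8 and 0 adjusted over the list alone, adjusted p = 2.58e-06, and adjusted p = 0.165 with an estimated correlation). Serpina3n (1.09) and Cp (0.87) were among them. For proliferation 6 of 20 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.00344, and adjusted p = 0.226 with an estimated correlation), with the replication licensing genes Mcm2 (0.88) and Mcm5 (0.79). For p53 targets 1 of 15 rose and 0 fell (5 and 0 adjusted over the list alone, adjusted p = 0.000344, and adjusted p = 0.226 with an estimated correlation). For cytokines, chemokines and adhesion molecules 2 of 20 rose and 0 fell (2 and 0 adjusted over the list alone, adjusted p = 0.00257, and adjusted p = 0.177 with an estimated correlation). In the loop, distal tubule and collecting duct list 0 of 20 rose and 6 fell (0 and 8 adjusted over the list alone, adjusted p = 4.46e-06, and adjusted p = 0.137 with an estimated correlation). Egf (-1.11) fell. No oxidative phosphorylation gene passed: 0 of 18 rose and 0 fell (0 and 0 adjusted over the list alone, adjusted p = 0.00286, and adjusted p = 0.504 with an estimated correlation). Heat shock genes (2 of 11 rose and 0 fell, 3 and 0 adjusted over the list alone, adjusted p = 0.00573, and adjusted p = 0.506 with an estimated correlation) no longer passed as a list without GR-deficient healthy replicate 2 (adjusted p = 0.127). Gluconeogenesis genes (0 of 10 rose and 2 fell, 1 and 3 adjusted over the list alone, adjusted p = 0.0322, and adjusted p = 0.544 with an estimated correlation) did not pass without GR-deficient AKI replicate 1 (0.0779) or healthy replicate 2 (0.0533) or 3 (0.14). The neutrophil list (0 of 13 rising and 0 falling, 0 and 0 adjusted over the list alone, camera adjusted p = 0.155) and the list of monocytes and macrophages (2 of 17 rising and 0 falling, 3 and 0 adjusted over the list alone, camera adjusted p = 0.11) did not pass, although Cd68 (1.28) and Cd14 (1.39) rose.

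**Figure D2:**
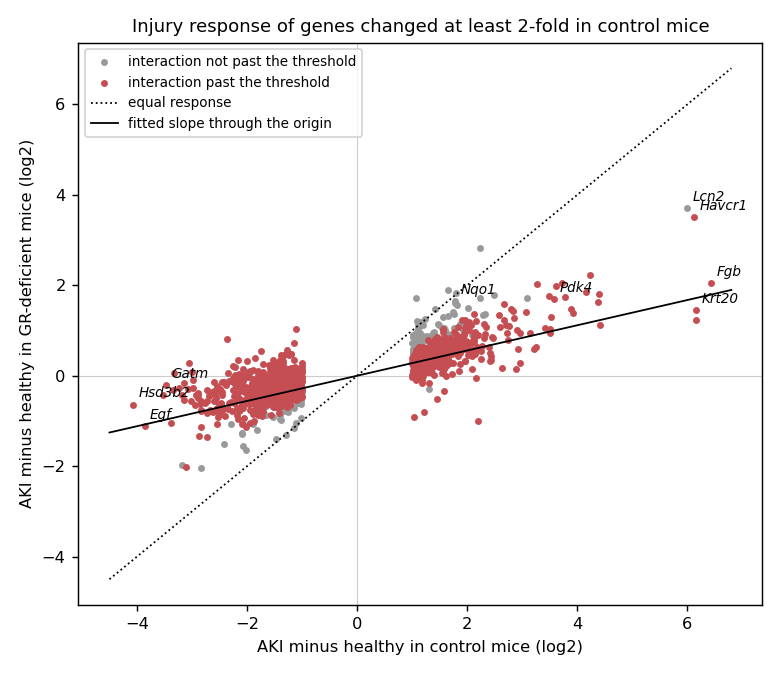
AKI minus healthy log2 difference in GR-deficient mice (y axis) against control mice (x axis) for the 1306 genes that passed and differed at least 2-fold in control mice, 1 point per gene, red where the interaction passed. The solid line is the slope of 0.279 through the origin, and 99.2% of these genes had the smaller response in GR-deficient mice. The choice of genes by their size in control mice favours such a share.

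The 2 responses share no array. Over the 1306 genes at least 2-fold changed in control mice, which were chosen for their size there, the response of GR-deficient mice was 0.279 of the control response (slope through the origin across genes, which are not independent replicates, Pearson r = 0.818). The sign was the same for 88.4% of them. Each GR-deficient AKI array lay well below 1 (0.351, 0.27 and 0.216), while each control AKI array set against the other 2 had a slope between 0.879 and 1.05. The genes were chosen in these same control arrays, and both sides of the control slopes share 1 healthy mean. This favours control slopes near 1, so they are no independent benchmark. The GR-deficient slopes all subtract the GR-deficient healthy mean, which includes replicate 1. The deviation of that array from the other 2 correlated with the control response over these genes (r = 0.431). It may therefore lower the GR-deficient slopes, and a slope without that array was not computed. Of the genes higher after AKI, 496 were shared by both genotypes against 89.1 for independent lists, and of the lower genes 235 against 40.7.

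GR deficiency was then compared within healthy mice. Akr1c18 (-2.20 ± 0.26), which inactivates progesterone, and Hsd11b1 (-1.21 ± 0.097), which regenerates active glucocorticoid, were lower. So were Hsd17b11 (-1.05 ± 0.17), a steroid dehydrogenase of lipid droplets, and Agps (-1.04 ± 0.15), an ether lipid enzyme. Lower too were Nat8f5 (-1.54 ± 0.24), Dbp (-1.19 ± 0.2), Chrdl1 (-1.11 ± 0.11), an inhibitor of bone morphogenetic proteins, Podn (-1.10 ± 0.18), a matrix proteoglycan, and Arsb (-1.04 ± 0.18), a lysosomal sulfatase. Higher were Rdh16f2 (1.65 ± 0.22), a retinol dehydrogenase relative, Pigr (1.27 ± 0.15), the receptor that carries immunoglobulin A across epithelium, and Clic6 (1.12 ± 0.19). Stk32a (0.92 ± 0.14), Gsta4 (0.85 ± 0.14), a glutathione transferase, Hpgd (0.77 ± 0.13), which degrades prostaglandins, and Fgfbp1 (0.58 ± 0.1) were higher too.

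In total 29 genes passed in healthy mice, 7 higher and 22 lower, and 13 differed at least 2-fold (3 and 10), with 2124 genes at an unadjusted p under 0.05. The 2-fold count was 7 without healthy control replicate 1, 6 without GR-deficient healthy replicate 1, 37 without GR-deficient healthy replicate 3, 8 on only the 6 arrays compared and 6 against a change above 1.2-fold. Over all probe sets 11 passed, 4 higher and 7 lower (36.4% higher against 24.1%). The count of genes that passed was 10 without healthy control replicate 1, 15 without either of the other 2 healthy control arrays, and 11, 18 and 115 without GR-deficient healthy replicates 1, 2 and 3. Of the 17 named genes that passed, Nr3c1, Hsd11b1, Chrdl1, Akr1c18, Rdh16f2 and Pigr passed in all 6 of these fits, and the other 11 lost the call in at least 2 of them.

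No glucocorticoid receptor target passed in healthy mice (0 of 23 measured members were higher and 0 were lower, 0 and 4 adjusted over the list alone, camera adjusted p = 0.885, adjusted p = 0.987 with an estimated correlation). The members with the smallest p were Dusp1 (-0.85 ± 0.17, adjusted p = 0.0644) and Klf9 (-0.53 ± 0.14, adjusted p = 0.179), and the median (0.0963) and mean (-0.0118) differed in sign. Proximal tubule genes were lower as a list without a single call over all genes: 0 of 23 measured members were higher and 0 were lower (0 and 5 adjusted over the list alone, camera adjusted p = 1.85e-07, adjusted p = 0.878 with an estimated correlation), with Slc5a2 (-0.71 ± 0.13, adjusted p = 0.0503) nearest. In the corticosteroid receptor list only Nr3c1 and Hsd11b1 passed: 0 of 10 were higher and 2 were lower (0 and 2 adjusted over the list alone, adjusted p = 0.00348, and adjusted p = 0.878 with an estimated correlation), and the list did not pass without GR-deficient healthy replicate 2 (0.0535). For circadian clock genes 0 of 15 were higher and 1 was lower (1 and 5 adjusted over the list alone, adjusted p = 0.00315, and adjusted p = 0.213 with an estimated correlation). Tubular injury markers had a median of 0.234: 0 of 19 were higher and 0 were lower (0 and 1 adjusted over the list alone, adjusted p = 0.0261, and adjusted p = 0.889 with an estimated correlation). This rested on GR-deficient healthy replicate 1, the array with raised Lcn2 and Havcr1, since the adjusted p was 0.662 without it. The gluconeogenesis list (0 of 10 were higher and 0 were lower, 0 and 0 adjusted over the list alone, adjusted p = 0.0161, and adjusted p = 0.889 with an estimated correlation) did not pass after quantile normalization (0.133) or cyclic loess (0.132). Podocyte genes (0 of 9 were higher and 0 were lower, 0 and 0 adjusted over the list alone, adjusted p = 0.0106, and adjusted p = 0.878 with an estimated correlation) did not pass as a list without GR-deficient healthy replicate 2 (0.0646) or 3 (0.126). No heme and antioxidant gene (0 of 15 higher and 0 lower, 1 and 1 adjusted over the list alone, camera adjusted p = 0.91) and no regulated cell death gene (0 of 19 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 0.556) passed.

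GR deficiency was also compared within AKI. GR-deficient mice held more of some genes that fell most after AKI in control mice: Hsd3b3 (3.39 ± 0.22), Hsd3b2 (2.97 ± 0.22), Gatm (3.18 ± 0.21), Sucnr1 (2.91 ± 0.2) and Egf (2.75 ± 0.13) were higher. So were Slc7a12 (4.88 ± 0.34), an amino acid transporter, Sfrp1 (3.01 ± 0.28), a secreted WNT inhibitor, Ces1g (2.97 ± 0.23), and Kynu (2.81 ± 0.29) and Acmsd (2.67 ± 0.24), enzymes of tryptophan breakdown. Lower were Krt20 (-4.46 ± 0.28), Fgb (-3.71 ± 0.39), Fgg (-3.53 ± 0.53) and Fga (-2.66 ± 0.32). The lipid droplet coat gene Plin2 (-2.79 ± 0.31), Saa1 (-2.59 ± 0.35), an acute phase protein, and Sprr2f (-2.57 ± 0.22) were lower too. So were the stress genes Plk3 (-2.60 ± 0.26), Atf3 (-2.42 ± 0.31) and Hspa1a (-2.39 ± 0.22).

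Of 19938 genes, 3460 passed, 1997 higher and 1463 lower in GR-deficient mice with AKI, and 568 differed at least 2-fold (381 and 187). Hsd11b1 was lower by about as much as in healthy mice (-1.23 ± 0.097 in AKI and -1.21 ± 0.097 in healthy mice, interaction -0.02, adjusted p = 0.967). Of the 7 genes higher in healthy GR-deficient mice, 5 were also higher in AKI (0.701 for independent lists), and of the 22 lower genes 6 were also lower (1.61), Nr3c1 itself among the 6. These comparisons share no array, but they share 1 variance estimate per gene, which favours overlap.

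Among glucocorticoid receptor targets in AKI, 3 of 23 measured members were higher and 13 were lower (3 and 13 adjusted over the list alone, camera adjusted p = 2.55e-05, adjusted p = 0.1 with an estimated correlation). The members with the smallest p were Map3k6 (-1.48), Pdk4 (-1.79), Mt2 (-1.18) and Mt1 (-0.95), all lower. Of tubular injury markers, 1 of 19 measured members was higher and 16 were lower (1 and 17 adjusted over the list alone, camera adjusted p = 3.05e-13, adjusted p = 0.1 with an estimated correlation). Sox9 (-2.12) and Plaur (-2.13) were lower beside Krt20. In the heme and antioxidant list, 1 of 15 was higher and 7 were lower (1 and 7 adjusted over the list alone, adjusted p = 0.00172, and adjusted p = 0.26 with an estimated correlation), and Hmox1 (-1.79), Srxn1 (-1.72), Txnrd1 (-1.0) and Slc7a11 (-2.34) were lower. Proximal tubule genes were higher: 18 of 23 were higher and 1 was lower (19 and 1 adjusted over the list alone, adjusted p = 5.66e-15, and adjusted p = 0.122 with an estimated correlation). Miox (1.62), Aqp1 (1.28) and the organic anion transporter Slc22a8 (1.94) were among them. The regulated cell death list did not pass (3 of 19 higher and 6 lower, 3 and 6 adjusted over the list alone, camera adjusted p = 0.248), and its members moved both ways, Dpep1 (1.31) upward and Mlkl (-1.48), Chac1 (-0.96) and Acsl4 (-0.82) downward.

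Further tubular and energy lists were higher in GR-deficient mice with AKI. For the loop, distal tubule and collecting duct 14 of 20 were higher and 1 was lower (16 and 1 adjusted over the list alone, adjusted p = 1.53e-10, and adjusted p = 0.1 with an estimated correlation). Slc12a1 (2.44) was higher. For oxidative phosphorylation 13 of 18 were higher and 0 were lower (17 and 0 adjusted over the list alone, adjusted p = 5.17e-10, and adjusted p = 0.122 with an estimated correlation). For gluconeogenesis 9 of 10 were higher and 0 were lower (9 and 0 adjusted over the list alone, adjusted p = 3.93e-07, and adjusted p = 0.122 with an estimated correlation). For fatty acid oxidation 8 of 18 were higher and 0 were lower (12 and 0 adjusted over the list alone, adjusted p = 7.44e-06, and adjusted p = 0.26 with an estimated correlation). Examples were Ndufs1 (0.73), Fbp1 (0.90), fructose bisphosphatase, and Fabp3 (1.67). Proliferation genes (5 of 20 were higher and 0 were lower, 5 and 0 adjusted over the list alone, adjusted p = 0.00408, and adjusted p = 0.186 with an estimated correlation) included Mcm6 (0.74) and Tyms (0.76). The interferon list (2 of 13 were higher and 0 were lower, 2 and 0 adjusted over the list alone, adjusted p = 0.0138, and adjusted p = 0.468 with an estimated correlation) no longer passed without control AKI replicate 1 (adjusted p = 0.183), GR-deficient AKI replicate 1 (0.0646) or replicate 2 (0.103).

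Stress and inflammation lists were lower. For acute phase and complement 1 of 16 was higher and 11 were lower (1 and 13 adjusted over the list alone, adjusted p = 7.33e-09, and adjusted p = 0.1 with an estimated correlation). Neutrophil genes (0 of 13 were higher and 8 were lower, 0 and 8 adjusted over the list alone, adjusted p = 4.04e-06, and adjusted p = 0.122 with an estimated correlation) included Retnlg (-1.36) and S100a9 (-1.26). The unfolded protein and integrated stress response (0 of 18 were higher and 9 were lower, 0 and 11 adjusted over the list alone, adjusted p = 1.77e-06, and adjusted p = 0.186 with an estimated correlation) was led by Ppp1r15a (-1.70) and Atf4 (-1.02), and for heat shock 0 of 11 were higher and 6 were lower (0 and 6 adjusted over the list alone, adjusted p = 0.000433, and adjusted p = 0.26 with an estimated correlation). For p53 targets 1 of 15 was higher and 6 were lower (1 and 9 adjusted over the list alone, adjusted p = 0.000351, and adjusted p = 0.186 with an estimated correlation). Among cytokines, chemokines and adhesion molecules 0 of 20 were higher and 7 were lower (0 and 7 adjusted over the list alone, adjusted p = 0.00172, and adjusted p = 0.122 with an estimated correlation). Cxcl1 (-1.90), a neutrophil attractant, and Il34 (-1.27) were among them. Cd68 (-1.70) and Cd14 (-2.11) were lower, although the list of monocytes and macrophages did not pass (1 of 17 higher and 4 lower, 1 and 4 adjusted over the list alone, camera adjusted p = 0.134), nor did endothelium (3 of 15 higher and 4 lower, 5 and 5 adjusted over the list alone, camera adjusted p = 0.817), podocytes (3 of 9 higher and 1 lower, 3 and 1 adjusted over the list alone, camera adjusted p = 0.132), lymphocytes (0 of 14 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 0.869) or skeletal muscle (0 of 10 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 0.984). Median and mean differed in sign for endothelium (-0.149 and 0.00621) and skeletal muscle (0.0176 and -0.00367).

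**Figure D3:**
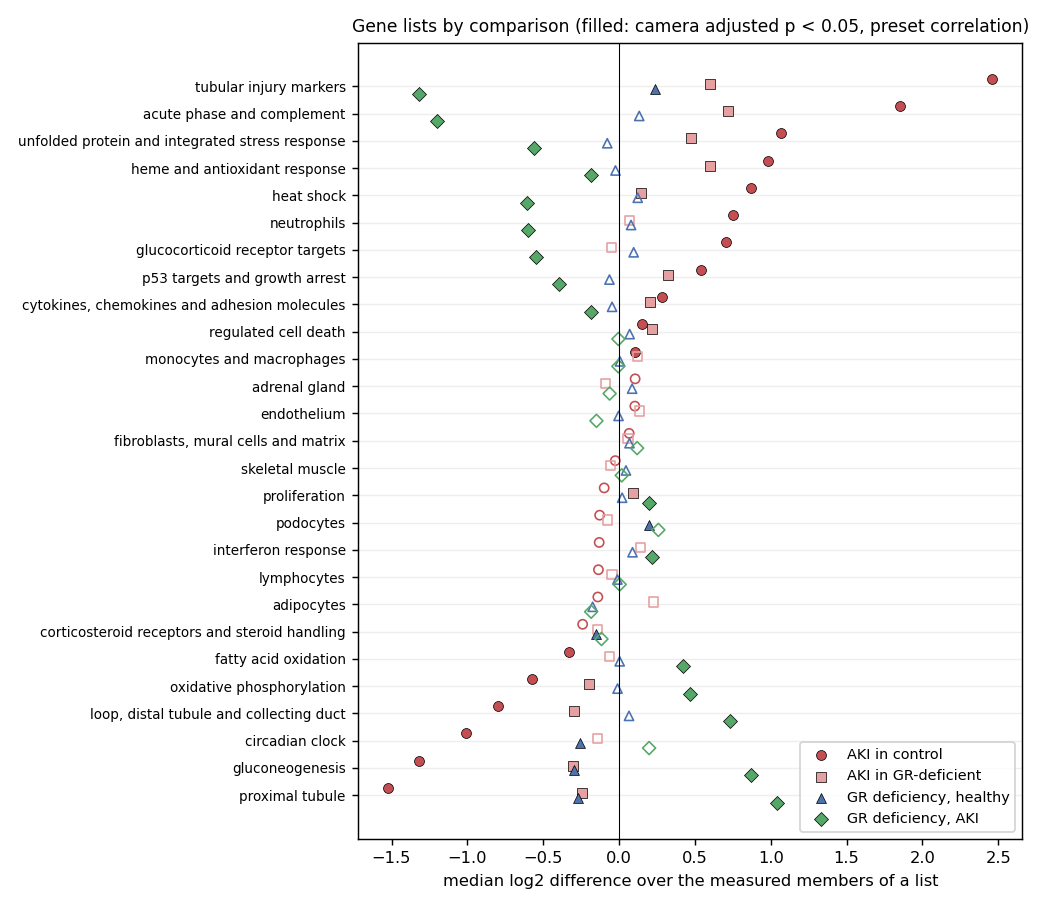
Median log2 difference over the measured members of 27 gene lists (x axis) in 4 comparisons (symbols), filled where camera passed with the preset correlation. The median of tubular injury markers was 2.46 for AKI in control mice, 0.601 for AKI in GR-deficient mice and -1.32 for GR deficiency in AKI.

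The interaction tested whether the AKI response differed between the genotypes, as the response of GR-deficient mice minus that of control mice. Some genes that fell in control mice had a less negative or a slightly positive response in GR-deficient mice. Among them were Hsd3b2 (3.43 ± 0.31), Hsd3b3 (3.39 ± 0.32), Gatm (3.26 ± 0.29), Sucnr1 (3.11 ± 0.28) and Egf (2.75 ± 0.19). Others were Acmsd (3.09 ± 0.34), Hykk (3.03 ± 0.41), Sectm1b (2.97 ± 0.36) and Cckar (2.89 ± 0.34), the cholecystokinin A receptor. Sfrp1 (3.32 ± 0.4) and Slc7a12 (3.18 ± 0.48) belonged to the same end of the ranking. Increases were smaller for Fgg (-4.92 ± 0.75), Krt20 (-4.70 ± 0.39), Fgb (-4.38 ± 0.55) and Fga (-3.30 ± 0.45). The same held for Lrg1 (-2.76 ± 0.4), Hspa1a (-2.75 ± 0.32), Plin2 (-2.63 ± 0.43), Havcr1 (-2.62 ± 0.66), Plk3 (-2.62 ± 0.37) and the macrophage gene Chil3 (-2.67 ± 0.45). For Lcn2 the interaction of -2.29 did not pass (adjusted p = 0.0726). Its size rests in part on GR-deficient healthy replicate 1, where Lcn2 was 9.94 against 7.09 in the other 2 arrays, which lowers the GR-deficient response. The same array enlarges the interactions of Havcr1 (8.11 against 6.39), Krt20 (6.46 against 5.35) and Fgb (7.44 against 6.36). Fgg was hardly raised there (8.21 against 8.15). The interaction calls of these 4 genes held in all 12 fits that left out 1 array.

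In all, 2283 genes passed the interaction test, 1473 above 0 and 810 below 0 (64.5% above 0, and 53% after quantile normalization with 1377 above and 1219 below). Nr3c1 differed by -0.20 ± 0.097 after AKI in GR-deficient mice (adjusted p = 0.307). It had an interaction of 0.50 ± 0.14 (adjusted p = 0.0299), a call that was lost in 6 of the 12 fits that left out 1 array, namely without control AKI replicate 2, healthy control replicates 1 or 3, GR-deficient AKI replicates 1 or 2 or GR-deficient healthy replicate 2. In the lists below, a member counted as above 0 had a less negative or larger positive response in GR-deficient mice.

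Proximal tubule genes had 19 of 23 above 0 and 0 below (20 and 0 adjusted over the list alone, camera adjusted p = 1.12e-19, adjusted p = 0.0974 with an estimated correlation). Miox (1.79), Slc34a1 (1.28), the phosphate transporter, and Slc7a13 (2.04) were among them. Tubular injury markers had 0 of 19 above 0 and 15 below (0 and 16 adjusted over the list alone, camera adjusted p = 3.97e-14, adjusted p = 0.0974 with an estimated correlation). Sox9 (-2.47), Sprr2f (-2.34) and Anxa2 (-1.63) were among them. Glucocorticoid receptor targets had 2 of 23 above 0 and 10 below (2 and 11 adjusted over the list alone, camera adjusted p = 0.000456, adjusted p = 0.0974 with an estimated correlation). Map3k6 (-1.63), Zbtb16 (-1.94), Mt2 (-1.41) and Mt1 (-1.20) were among them. The heme and antioxidant list had 0 of 15 above 0 and 4 below (0 and 5 adjusted over the list alone, camera adjusted p = 0.00692, adjusted p = 0.315 with an estimated correlation), and the members below 0 were Hmox1 (-2.04), Srxn1 (-1.73), Txnrd1 (-1.04) and Slc7a11 (-2.30). The regulated cell death list did not pass, with 1 of 19 above 0 and 5 below (2 and 7 adjusted over the list alone, camera adjusted p = 0.166, adjusted p = 0.275 with an estimated correlation) and Dpep1 (1.24), Chac1 (-1.10), Mlkl (-1.59) and Acsl4 (-0.91) as examples. Its median (0.0324) differed in sign from its mean (-0.26) and from the direction of its test. Clock genes had 6 of 15 above 0 and 2 below (7 and 3 adjusted over the list alone, camera adjusted p = 0.00826, adjusted p = 0.107 with an estimated correlation). Hlf (2.02) and Tef (1.72) were among them. Among corticosteroid handling genes, Hsd11b2 (1.26) was above 0 and Fkbp5 (-1.40), a GR co-chaperone, below. The call of Fkbp5 was lost in 5 of the 12 fits without 1 array (control AKI replicate 2, healthy control replicates 1 or 2, GR-deficient AKI replicates 2 or 3).

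Energy and distal lists had responses above 0. Gluconeogenesis had 8 of 10 above 0 and 0 below (9 and 0 adjusted over the list alone, camera adjusted p = 5.59e-08, adjusted p = 0.107 with an estimated correlation). The loop, distal tubule and collecting duct had 10 of 20 above 0 and 1 below (14 and 2 adjusted over the list alone, camera adjusted p = 4.92e-07, adjusted p = 0.0974 with an estimated correlation). Oxidative phosphorylation had 8 of 18 above 0 and 0 below (12 and 0 adjusted over the list alone, camera adjusted p = 4.11e-07, adjusted p = 0.16 with an estimated correlation). Fatty acid oxidation had 4 of 18 above 0 and 0 below (7 and 0 adjusted over the list alone, camera adjusted p = 0.000141, adjusted p = 0.315 with an estimated correlation). Stress lists lay below 0. Acute phase and complement had 1 of 16 above 0 and 11 below (1 and 11 adjusted over the list alone, camera adjusted p = 2.35e-09, adjusted p = 0.0974 with an estimated correlation). The unfolded protein and integrated stress response had 0 of 18 above 0 and 6 below (0 and 9 adjusted over the list alone, camera adjusted p = 0.000125, adjusted p = 0.275 with an estimated correlation). Heat shock had 0 of 11 above 0 and 5 below (0 and 6 adjusted over the list alone, camera adjusted p = 0.000148, adjusted p = 0.275 with an estimated correlation), and neutrophils had 0 of 13 above 0 and 7 below (0 and 8 adjusted over the list alone, camera adjusted p = 9.82e-06, adjusted p = 0.107 with an estimated correlation). The p53 list had 0 of 15 above 0 and 4 below (1 and 5 adjusted over the list alone, camera adjusted p = 0.00826, adjusted p = 0.314 with an estimated correlation) and did not pass without control AKI replicate 3 (0.0732). Cytokines, chemokines and adhesion molecules had 0 of 20 above 0 and 5 below (0 and 5 adjusted over the list alone, camera adjusted p = 0.0171, adjusted p = 0.249 with an estimated correlation), and this list did not pass after quantile normalization (0.0585), after cyclic loess (0.0661) or without GR-deficient AKI replicate 3 (0.109). Proliferation genes had 3 of 20 above 0 and 0 below (4 and 0 adjusted over the list alone, camera adjusted p = 0.0355, adjusted p = 0.314 with an estimated correlation), a call lost in 5 of the 12 fits without 1 array, with the largest p without control AKI replicate 3 (0.112). The lists of monocytes and macrophages (0.0657) and of the interferon response (0.062) did not pass.

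Averaged over healthy and injured mice with equal weight, GR deficiency mixed the small effect in healthy mice with the large one in AKI. Genes such as Slc7a12 (3.29 ± 0.24), Rdh16f2 (1.83 ± 0.16), Car3 (1.78 ± 0.28), Hsd3b3 (1.70 ± 0.16), Kynu (1.68 ± 0.21), Ces1g (1.62 ± 0.16) and Spp2 (1.55 ± 0.1), a secreted phosphoprotein, were higher. Krt20 (-2.11 ± 0.19), Mfsd2a (-1.77 ± 0.21), a lysophospholipid transporter, Akr1c18 (-1.74 ± 0.18), Ctxn3 (-1.64 ± 0.14), Ttpa (-1.64 ± 0.17), the vitamin E transfer protein, and Hsd11b1 (-1.22 ± 0.068) were lower. In all 1686 genes passed, 905 higher and 781 lower, 75 of them at least 2-fold (49 and 26, and 115 in all over all probe sets). The share of higher genes was 53.7%, and it was 67% against a change above 1.2-fold (146 and 72). The larger side was the lower one after centring arrays on their medians (754 higher and 808 lower), over all probe sets (630 and 688) and without control AKI replicate 1 (888 and 947), and 1079 passed without GR-deficient AKI replicate 3.

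Of the glucocorticoid receptor targets 0 of 23 measured members were higher and 9 were lower (2 and 11 adjusted over the list alone, camera adjusted p = 8.42e-05, adjusted p = 0.146 with an estimated correlation) on average, with Map3k6 (-0.66), Dusp1 (-0.79), Fkbp5 (-0.92) and the clock gene Per1 (-0.47) lower. For tubular injury markers 1 of 19 was higher and 10 were lower (1 and 14 adjusted over the list alone, adjusted p = 9.39e-10, and adjusted p = 0.155 with an estimated correlation). For the heme and antioxidant response 1 of 15 was higher and 7 were lower (1 and 7 adjusted over the list alone, adjusted p = 0.00179, and adjusted p = 0.295 with an estimated correlation). For the proximal tubule 9 of 23 were higher and 1 was lower (13 and 2 adjusted over the list alone, adjusted p = 7.46e-08, and adjusted p = 0.266 with an estimated correlation). Regulated cell death genes did not pass as a list (2 of 19 higher and 4 lower, 2 and 5 adjusted over the list alone, camera adjusted p = 0.384).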

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

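The tests of array scale, exchanged labels and single arrays behind the smaller response, both tests of GR-deficient healthy replicate 1 and the test of time of day for Dbp were chosen after the results had been seen. The label splits and the test of single arrays for Dbp were set before.

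The AKI response differed between control and GR-deficient mice for 2283 genes, by the interaction test itself. For this, 100 of 200 splits by genotype label within each condition were used, the real one and others drawn at random. Only the real one gave as many genes, a share of 1 in 100, with 1686 for the highest other drawn. That other split turns the labels in 1 condition and tests the average. Most other drawn splits gave 0 genes, and the rest gave from 1109 to 1686. The splits move genotype labels in both conditions, so the share speaks against chance for a genotype effect of some kind. It cannot exclude chance for the interaction as such, and the splits not drawn were not counted. For the average of 1686 genes 4 of the 100 drawn splits gave as many, the real one included, with 2283 (the interaction), 1905 and 1847 for the others. Chance is not excluded there, since that share rests on 1 gene (another split gave 1685). In addition, 3 drawn splits gave more genes than the real one, and only 100 of the 200 splits were drawn. For each of the 4 comparisons of 2 groups, 1 of 10 splits, the real one, gave as many genes, against highest others of 0 for AKI in control mice, 0 for AKI in GR-deficient mice, 2 for GR deficiency in healthy mice and 0 for GR deficiency in AKI, and 10 splits are too few for a share under 0.05.

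By the same test 16 lists differed with the preset correlation and none with an estimated one. Medians above 0 were 1.36 for proximal tubule, 0.975 for gluconeogenesis, 0.671 for loop, distal tubule and collecting duct, 0.512 for circadian clock, 0.446 for oxidative phosphorylation, 0.4 for fatty acid oxidation and 0.18 for proliferation. Medians below 0 were -1.63 for tubular injury markers, -1.17 for acute phase and complement, -0.699 for heat shock, -0.683 for neutrophils, -0.638 for glucocorticoid receptor targets, -0.562 for the unfolded protein and integrated stress response, -0.371 for p53 targets and growth arrest, -0.121 for heme and antioxidant response and -0.105 for cytokines, chemokines and adhesion molecules.

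Of 148 genes named in the report and the closing section, 109 had a response that differed between the genotypes, 54 above 0 and 55 below 0 in GR-deficient minus control mice. Most were named because they were extreme in a comparison, which favours such a difference. The largest values were Hsd3b2 (3.43), Hsd3b3 (3.39), Sfrp1 (3.32), Gatm (3.26), Slc7a12 (3.18), Sucnr1 (3.11), Acmsd (3.09), Hykk (3.03), Sectm1b (2.97), Cckar (2.89), Egf (2.75) and St8sia1 (2.74). Next came Ces1g (2.72), Slc12a1 (2.41), Cndp1 (2.34), Dbp (2.33), Kynu (2.26), Slc51a (2.16), Slc7a13 (2.04), Hlf (2.02), Slc22a8 (2.02), Map2k6 (1.97), Fabp3 (1.83) and Miox (1.79). They were followed by Tef (1.72), Spp2 (1.67), Ugt2b34 (1.60), Fcamr (1.54), Podn (1.53), Slc5a2 (1.43), Akr1c14 (1.38), Rsad2 (1.36), Aqp1 (1.34), Nat8f5 (1.28), Slc34a1 (1.28) and Hsd11b2 (1.26). Closer to 0 were Dpep1 (1.24), Arsb (1.21), Hsd17b11 (1.19), Clic5 (1.18), Ttr (1.07), Fbp1 (1.02), Agps (0.98), Klf15 (0.92), Hpgd (0.77), Chrdl1 (0.77), Ndufs1 (0.76) and Mcm6 (0.74). The smallest included Mdh1 (0.69), Mcm5 (0.62), Kdr (0.59), Mcm2 (0.59), Nr3c1 (0.50) and Sdhb (0.47). Furthest below 0 lay Fgg (-4.92), Krt20 (-4.70), Fgb (-4.38), Fga (-3.30), Lrg1 (-2.76), Hspa1a (-2.75), Chil3 (-2.67), Plin2 (-2.63), Havcr1 (-2.62), Plk3 (-2.62), Hspb1 (-2.58) and Cd14 (-2.53). Less far below were Sox9 (-2.47), Atf3 (-2.46), Sprr2f (-2.34), Slc7a11 (-2.30), Plaur (-2.24), Hmox1 (-2.04), Akr1b8 (-1.99), Saa1 (-1.96), Cxcl1 (-1.94), Zbtb16 (-1.94), Pdk4 (-1.89) and Ppp1r15a (-1.74). Then came Srxn1 (-1.73), Timp1 (-1.69), Anxa2 (-1.63), Tnfrsf12a (-1.63), Map3k6 (-1.63), Mlkl (-1.59), Cd68 (-1.57), S100a8 (-1.50), Il6 (-1.47), Retnlg (-1.43), Mt2 (-1.41) and Ttpa (-1.40). Smaller differences were Fkbp5 (-1.40), Stk32a (-1.37), Btg2 (-1.30), Atf4 (-1.30), Serpina3n (-1.26), Aldh1a2 (-1.24), S100a9 (-1.21), Mt1 (-1.20), Ctxn3 (-1.12), Chac1 (-1.10), Txnrd1 (-1.04) and Arntl (-1.04). Closest to 0 were Asns (-0.95), Il34 (-0.93), Acsl4 (-0.91), Nos3 (-0.77), Sult1d1 (-0.71), Col3a1 (-0.68) and Fgfbp1 (-0.64).

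The smaller response of GR-deficient mice could come from the arrays, the labels or the injury. A scale that shrank every response by 1 factor is excluded as the whole cause, since at least 69 genes deviated from every factor from 0 to 1. A compression of the GR-deficient AKI arrays alone would shift genes by their expression level, and this was not tested. Exchanged genotype labels among the AKI arrays are excluded by a gap of 0.72 in Nr3c1 between the lowest control and the highest GR-deficient AKI array. A single less injured array is excluded as the cause, since the highest of the 3 response slopes was 0.351. A milder injury of the whole GR-deficient group, or of 1 mouse behind all 3 arrays, was not tested and stays open beside the hypothesis that tubular GR enlarges the response. An effect of Pax8-Cre itself cannot be told apart from loss of GR by this design.

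In GR-deficient healthy replicate 1, injury genes such as Lcn2, Havcr1 and Krt20 were raised. RNA of an injured GR-deficient kidney mixed in would raise all injury genes by a shared portion. Of the 93 genes at least 2-fold up after AKI in GR-deficient mice, 32.3% lay at or below the other 2 healthy arrays. A small admixture is not excluded by this share, since the median deviation of these genes was 0.17. The SD of this array's deviation from its group mean was 0.196 over all genes, so noise alone can place such genes below the others. Hmox1 (9.41 against 9.41) was not raised. A label exchanged with a GR-deficient AKI array is excluded by a slope of 0.267 on the AKI response, where the lowest AKI array had 0.88. Another earlier or milder injury of this mouse may have raised them and was not tested.

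Dbp was lower in healthy GR-deficient mice and, like other clock output genes, depends on the hour. A single array is excluded as the cause of its size, since 83.2% of the difference was kept in the fit that kept the least, but it lost its call in 3 of 6 such fits (adjusted p up to 0.164), without control healthy replicate 1 or 2 or GR-deficient healthy replicate 1. Another time of day at dissection could not be excluded or shown: all 9 of the 9 clock genes that move with Dbp were lower, but only Dbp passed, and of the genes of the opposite phase Arntl was higher (0.61) and Clock was not (-0.09). An effect of GR on Dbp itself stays open.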

How the results depend on the processing

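The fit without the 2 doubted arrays was chosen after the arrays had been seen, and all other alternatives were set before. No named gene and no list turned its direction while past the threshold. The larger side of the counts turned for AKI in control mice after quantile normalization and over all probe sets, and for the average after centring, over all probe sets and without control AKI replicate 1. Arrays centred on their medians, the mean of a gene's probe sets and quantile normalization left all 6 gene counts and all 6 list counts within 1.5 times their value. Array quality weights gave 9648 genes for AKI in control mice, 3196 for AKI in GR-deficient mice, 301 for GR deficiency in healthy mice, 7000 for GR deficiency in AKI, 4905 for the interaction and 4355 for the average. Weights were lowest for control AKI replicate 1 (0.182) and GR-deficient healthy replicate 1 (0.296) and highest for control AKI replicate 2 (5.09). A test against a change above 1.2-fold gave 2870, 153, 7, 1244, 916 and 218 genes in the same order, fewer by construction. For GR deficiency in healthy mice, the count was 11 over all probe sets, 62 with dim genes left out, 61 after cyclic loess, 71 with an intensity trend and robust prior and 14 on only the 6 arrays compared, and fry called 2 lists. With the inter-gene correlation estimated, 0 lists passed in each of the 6 contrasts. Apart from the minimum change, the cause was not tested. With each array left out in turn, the counts ranged from 4651 to 6008 for AKI in control mice, 277 to 920 for AKI in GR-deficient mice, 10 to 115 for GR deficiency in healthy mice, 2414 to 3699 for GR deficiency in AKI, 1556 to 2696 for the interaction and 1079 to 1943 for the average. Lists that passed ranged from 16 to 17, 12 to 16, 5 to 7, 15 to 16, 15 to 17 and 16 to 18. Named genes that passed in all such fits were 69 of 73, 39 of 57, 6 of 17, 67 of 69, 66 of 70 and 59 of 65. Without the 2 doubted arrays together, 6974, 1291, 26, 3934, 2351 and 2045 genes passed, and the 2-fold count for GR deficiency in healthy mice fell from 13 to 7. Other 2-fold counts stayed within 1.5 times except where the report gives the value. With the replicate number as a block (replicate block), 5368, 671, 25, 3104, 2013 and 1418 genes passed. The numbers do not pair the samples in these data: of 18 pairs with the same number 3 had r above 0.1 (range -0.41 to 0.25), and 3 of 12 arrays correlated best with their own number. Among named genes, 77 calls were lost under the minimum change, 33 over all probe sets, 18 on the 6 arrays compared, 12 with the block, 7 after quantile normalization and 4 after cyclic loess. Precision is limited by 3 arrays per group, and signal over background was not analysed here.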

Other observations

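The tests of the same sign and of the overlap in healthy and injured mice were chosen after these genes had been seen. The search over all factors was chosen after the count of deviating genes had been seen. The tests of deviation from the fitted factor and of the glucocorticoid receptor targets were set before their results.

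Some genes responded to AKI in GR-deficient mice beyond the common factor of 0.279. The largest deviations were Ces1g (2.42), Kynu (1.74), Slc16a6 (1.44), Akr1c12 (1.41), Ugt2b34 (1.37), Slc51a (1.35), Blvrb (1.33), which encodes biliverdin reductase B, and Maoa (1.32), a monoamine oxidase. Ces1g rose by 2.31 in GR-deficient mice and differed by -0.41 in control mice. The antioxidant genes Nqo1 (1.16) and Gsta4 (1.11) rose about as much in both genotypes (Nqo1 by 1.66 and 1.78, Gsta4 by 1.61 and 1.77 in GR-deficient and control mice). Deviations below 0 were fewer, with Ttr (-1.16), Upp2 (-1.08), Sult1d1 (-1.05), a sulfotransferase, and Cyp7b1 (-0.83), an oxysterol hydroxylase. As a list, heme and antioxidant response had a median deviation of 0.383 (2 members up, camera adjusted p = 6.65e-09, and 0.349 with an estimated correlation), proliferation 0.117 (2 up, 0.00212 and 0.349), proximal tubule 0.17 (0 up, 0.0317 and 0.898) and interferon response 0.242 (0 up, 0.049 and 0.898).

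A response of GR-deficient mice equal to the control response times 1 factor for every gene is excluded. By the bounds set beforehand it allowed fewer than 20 deviating genes and was to be excluded from 100, and the 79 that deviated from the fitted factor (70 above and 9 below 0) missed the second bound. The exclusion rests on the later search, where over all factors from 0 to 1 the fewest were 69, at a factor of 0.36, and also 69 without the 2 doubted arrays, at 0.41. The count was 161 with the factor divided by 1.5, 98 with the factor times 1.5 and 114 without the 2 doubted arrays, so its size depends on the factor, which was fitted on genes chosen for their size in control mice. Why these genes deviate was not tested. Of the 2283 genes with an interaction, 43 also deviated.

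Whether glucocorticoid receptor targets depart from the common factor was tested on the deviation of the list. Camera gave p = 0.057 with the preset correlation and p = 0.17 with an estimated correlation, at a median deviation of -0.145. Targets that follow the general decrease of the response are consistent with this value, and a departure was not shown and is not ruled out. The largest deviation of a member was that of Bcl6 (-1.29, response -0.42 in control and -1.41 in GR-deficient mice, adjusted p = 0.371). The largest deviations among members with opposite responses were those of Zbtb16 (-1.20, response 1.03 in control and -0.91 in GR-deficient mice, adjusted p = 0.0509) and Fkbp5 (-0.87, response 0.74 and -0.66, adjusted p = 0.216).

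An effect of GR deficiency that does not need injury would keep its sign in AKI. Of the 28 genes other than Nr3c1 that passed in healthy mice, 10 passed in AKI with the same sign, against 2.24 for independent lists (permutation of genes, p = 8e-05), and 3 with the opposite sign, against 2.62. In fits on only the 6 arrays compared 5 passed in both with the same sign, against 0.824 (permutation of genes, p = 0.00086). The overlap thus exceeded that of lists drawn at random over genes. Both permutations treat genes as independent and equally likely to pass, so shared regulation or unequal variance of genes may add to it. Over all 28 genes 19 had the same sign (67.9%), between the bounds of 50% and 80% (exact binomial p = 0.0872), so for signs alone unrelated effects cannot be told apart from shared ones with so few genes. Among the 10 were Hsd11b1 (-1.21 in healthy mice, -1.23 in AKI), Akr1c18, Rdh16f2, Pigr, Clic6, Hpgd and Gsta4. Dbp (1.14 in AKI, -1.19 in healthy mice), Map2k6 (1.23 and -0.74) and Stk32a (-0.46 and 0.92) passed with opposite signs.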
